A study of Homo sapiens with 2 samples.

How the data were processed

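RIP-seq was carried out in A549 cells on 2 samples, 1 HNRNPC IP library and 1 input library, which formed a group each, per the labels. The peak list of the IP library was analysed; the input sample's own values were not used here. HISAT2, MACS2 and bedtools and build hg38 are named per the submitters' processing notes, with no version, role or setting given in the sources used here, and whether the input served as the control is likewise not stated. The deposited list holds 1 row per peak with its position, its summit, a score, a fold enrichment (a ratio over the background the caller used), and the −log10 of p and of q. In the deposited file the score is the integer part of 10 times the −log10 q in all 23148 rows. No row has a strand and no region occurs more than once. The read totals are not given in the list, so depth is unknown and no value has an error between replicates. Intervals on shares are 95% exact Clopper-Pearson binomial intervals, and intervals on densities are exact Poisson intervals, both of which cover counting error only. Neighbouring peaks of a gene are not independent, which such intervals ignore.

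Peaks on chromosomes 1 to 22, X and Y were kept (23111); 37 peaks on 5 other contigs were counted apart and none lay on the mitochondrial chromosome. Coordinates are 1-based. Genes came from a RefSeq table of GRCh38 patch 14, with 59679 genes on these chromosomes, which gives gene spans without exons or strand. A peak belonged to the gene whose span held its summit, protein-coding genes before other biotypes; where several remained the peak was shared and counted for none. Of all peaks, 22227 belonged to a single gene.

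The gene lists, the rule for named genes and most alternatives were fixed before the data were examined; the alternatives chosen later are named with their effect. The rule named E2F2 and HNRNPC, the 10 protein-coding or lncRNA genes with the highest fold among the peaks in the upper part of the list by q, the 10 genes with the most peaks, up to 4 members of each gene list by fold with members whose absence mattered, and the genes of the 10 peaks of lowest q. Some items that the rule would name are not reported here. Each of 19 lists was set beside 10000 random lists of the same size, biotype and span class (10 classes per biotype, seed 20); a list was called above the random lists when at most 2.5% of these had as many members with a peak. The percentile describes this library only and carries no test. All symbols of the lists were found in the reference. Medians of the members' best folds were set beside random genes with a peak in the same way where a list had enough such members. The plan called for matching on exon length. Gene span took its place, and gene number took the place of exon length for the chromosomes. Planned results on transcript features, U-tracts, DRACH sites, Alu elements and the stop codon need sequence or transcript structure and were not analysed here. The position of peaks in the gene span was added after the data were seen.

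The list procedure was tested on simulated data over 59679 genes: of 200 random lists of 20 genes without an excess, 1.5% stood apart, and of 200 with a planted excess, 98.5%. Simulated peaks depended on span class alone, with independent genes, and the planted excess was large. These rates therefore do not cover lists that differ in expression or have a small excess. Alternatives were q of 0.001 or less, a fold of 4 or more, other rules of overlap, shared peaks counted for each gene, unmatched lists and all contigs. Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.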

Results

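RNA bound to HNRNPC was profiled by RNA immunoprecipitation sequencing (RIP-seq) in A549, an established human non-small cell lung cancer cell line. HNRNPC is a nuclear RNA-binding protein of the hnRNP family that is known to bind runs of U, and the series concerns its role as a reader of N6-methyladenosine (m6A) and its relation to E2F2, a transcription factor of the cell cycle. The series has 2 samples, 1 library from the immunoprecipitate (IP) made with 5 µg of antibody and 1 input library. The values used here are the peaks of the IP library; the input library's own values were not analysed here. With 1 library per group there was no replicate check, no test between samples was made and no p-value is given. The peak list gives no read totals, so the depth of the libraries is unknown. Fold enrichment and q are the authors' values for each peak and serve here only to describe and rank peaks within this list.

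The list held 23148 peaks, of which 23111 lay on chromosomes 1 to 22, X and Y of human genome build 38. Peaks were short, with a median width of 125 bp (quartiles 80 and 198 bp), although 584 were 1000 bp or wider. The median fold enrichment was 5.76, with quartiles 4.79 and 7.22 and a highest value of 31.5. The highest q in the list was 0.00998.

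HNRNPC peaks lay almost entirely within genes. Of the 23111 summits, 22797 (98.6%, 95% exact binomial interval 98.5 to 98.8%) lay within an annotated gene span, whereas random positions between the first and last gene of each chromosome gave a mean of 56.2% and at most 57.1% in 1000 placements. Density was 13.6 peaks per Mb inside gene spans and 0.223 per Mb between them. Random positions take no account of where RNA is transcribed, and the share for the input was not analysed. Whether the excess within genes is particular to HNRNPC therefore cannot be told. A single protein-coding gene held 21769 summits (94.2%), and 570 (2.47%) were shared by several genes. A single lncRNA gene, with no protein-coding gene at the summit, held 357 (1.54%). Median fold was 5.76 in protein-coding genes, 5.27 in lncRNA genes and 5.40 for the 314 peaks with their summit outside genes, 29 of which overlapped a gene span with another part. These intervals cover counting error only. Exons, introns and UTRs were not resolved, because the reference used here holds gene spans without transcript structure or strand.

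Peaks were carried by 3440 of 20037 protein-coding genes (17.2%) and by 91 of 18303 lncRNA genes (0.497%). A summit within both a protein-coding and a lncRNA span counted for the protein-coding gene only. The shares of these biotypes are therefore not directly comparable, and expression was not measured. Many genes held several peaks. The 763 genes with 10 or more held 56.4% of all peaks assigned to a single gene, while 868 genes (24.2%) held 1. PDE4D, which encodes a cAMP phosphodiesterase, had the most peaks, 88 over a span of 1553091 bp. It was followed by PRKDC, the DNA-dependent protein kinase catalytic subunit, with 71, and by ASPH with 66. BIRC6 and VPS13C had 59 each, the ubiquitin ligase gene HUWE1 had 58, DOCK5 and SMG1 had 57 each, TNS3 had 51 and FBN2 had 50. SMG1 has closely similar pseudogene copies, so its count is uncertain. Relative to span, SMG1 (46.9 peaks per 100 kb), PRKDC (38.0) and HUWE1 (37.5) were more densely covered than PDE4D (5.67).

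The peaks of highest fold lay in genes of several kinds. The highest fold, 31.5, belonged to H4C3, a replication-dependent histone H4 gene, in a peak at chromosome 6, 26103945 to 26104316, that covered most of its 405 bp span. PTBP3, a paralog of the polypyrimidine tract-binding protein, had a peak of 25.8 at chromosome 9, 112232064 to 112232255. DPYSL2 reached 25.3, PDE4D 24.7, the nuclear export receptor gene XPO1 24.3, PPP1CB 23.7, CACUL1 23.2, HP1BP3 22.5, the linker histone gene H1-3 22.03 and CCDC6 21.6. Genes of the first 7 of these also held the peaks of lowest q. At the highest peak of each gene named here, the control level inferred from fold and p (the background at the summit) was 0.376 or lower. Under that inference no control read lay over these summits, so their folds may follow IP coverage more than enrichment.

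E2F2 carried 10 peaks. The gene (NCBI gene 1870) spans chromosome 1, 23505212 to 23531233, and its strongest peak, 1798 bp wide at 23508049 to 23509846, had a fold of 8.53 and a −log10 q of 10.8. This peak ranked 3504 of 23111 by fold, so 15.4% of all peaks were at least as high. A narrow peak nearby at 23507385 to 23507454 had a fold of 7.12, and a peak at 23530594 to 23531292, at the other end of the span, had 7.75. The remaining 7 E2F2 peaks had folds from 4.25 to 6.73. By best fold E2F2 ranked 1147 of the 3588 genes with a peak. Among 2004 protein-coding genes of its span class (24.1 to 35.3 kb), 32 genes (1.60%), E2F2 included, had 10 or more peaks. Only 373 genes of this class had any peak, and expression was not matched. The median fold of the 10 E2F2 peaks was 5.52, against 5.76 for all peaks. With q of 0.001 or less E2F2 kept 6 peaks.

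HNRNPC itself carried 18 peaks. Its gene (NCBI gene 3183) spans chromosome 14, 21209147 to 21269442. The strongest peak, at 21247885 to 21247964, had a fold of 7.22 and ranked 5655 by fold, and the widest, at 21262642 to 21263807, had 6.58. The median fold of the 18 was 5.25. In the span class of HNRNPC (52.3 to 83.5 kb), 33 of 2004 genes (1.65%), HNRNPC included, had as many peaks, and 604 had any peak.

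**Figure D1:**
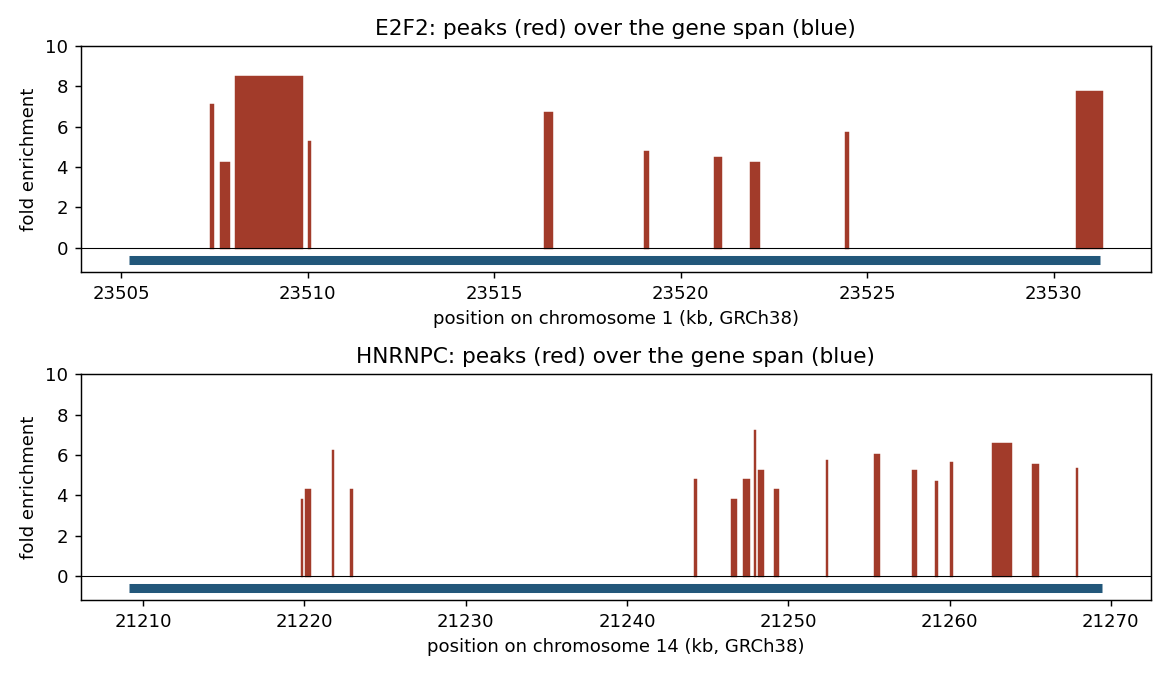
Peaks over E2F2 (top) and HNRNPC (bottom): the x axis is the chromosome position in kb, bar width is the peak's extent, bar height the authors' fold enrichment, and the blue line the gene span. E2F2 held 10 peaks with folds up to 8.53 and HNRNPC 18 with folds up to 7.22.

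Several regulatory gene groups carried peaks more often than random lists of genes of the same biotype and span class. Expression was not matched for any list, so the counts for this and the following lists combine expression with enrichment. Among the E2F and pocket proteins, which control entry into S phase, 8 of 13 had a peak against a mean of 3.09 in random lists, and 20 of 10000 random lists had as many. The members with the highest folds were RBL2 (15.5), RBL1 (10.1), E2F3 (8.67) and E2F2 (8.53). E2F1 had no peak. Of the cell cycle and DNA replication genes 18 of 47 had a peak (random mean 7.31, 0 of 10000 as high), led by CDK6 (17.4), TOP2A (16.0), GINS1 (13.3) and MCM10 (13.0). As the median of the best folds of these 18 was 5.67, against a median of 6.76 for random genes with a peak, they were set apart by number and not by fold. Fold also depends on the background at the summit, so it does not measure strength of binding alone.

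The m6A machinery was also covered. Peaks lay in 7 of 11 writer and eraser genes (random mean 2.22, 7 of 10000 as high), with the highest folds in FTO (11.1), a demethylase, RBM15 (9.19), VIRMA (8.39) and METTL16 (8.19), while the methyltransferase genes METTL3 and METTL14 had none. Of the m6A readers 9 of 14 had a peak (random mean 3.19, 5 of 10000 as high), among them FMR1 (12.6), IGF2BP3 (9.16) and YTHDF3 (7.997). Of the hnRNP genes 11 of 27 had a peak (random mean 4.03, 8 of 10000 as high), led by PTBP3 (25.8), HNRNPR (9.41), PCBP2 (9.30) and PTBP2 (9.16). Of the SR proteins and U2 factors, which act in splicing, 9 of 26 had a peak (random mean 3.48, 37 of 10000 as high), led by SRRM1 (11.99) and SF3B1 (10.1). HNRNPC is in both the reader and the hnRNP list. The median best fold was 6.12 for the readers and 5.86 for the hnRNP genes with a peak. Random genes with a peak had 7.03 and 6.93, and 8425 and 8959 of 10000 random lists were as high. The readers and hnRNP genes thus stood apart by number and not by fold. Over all peaks the median fold was 6.24 where no control read was inferred over the summit and 2.49 at an inferred control level of 10 or more. Lower folds therefore do not show weaker binding.

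Lung cancer driver genes and NRF2 targets also carried peaks more often than random lists, and the epithelial-mesenchymal genes did not pass that bar. Peaks lay in 12 of 22 lung cancer driver genes (random mean 5.94, 44 of 10000 as high). Among them were MET at a fold of 16.7, NF1 at 14.01 and EGFR at 13.0. The 10 drivers without a peak included CDKN2A and CDKN2B, for which neither expression nor copy number was analysed here. NF1 held 50 peaks and EGFR 22. Of the targets of NRF2, the regulator of the antioxidant response, 10 of 26 had a peak (random mean 4.29, 39 of 10000 as high), with ABCC2 at 14.5, the cystine transporter gene SLC7A11 at 10.4 and TXNRD1 at 9.62 over 26 peaks. The median best fold of these targets was 6.002, against 6.97 for random genes with a peak (8825 of 10000 as high). Of the epithelial-mesenchymal genes 7 of 18 had a peak, which 344 of 10000 random lists equalled, above the 2.5% allowed, and their median best fold of 10.7 was equalled by 233 of 10000 random lists. ITGB1 (14.5), OCLN (13.3) and TGFB2 (12.5) led this group.

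Relative to their random means, noncoding RNAs and histones stood apart most, again without a match on expression. Of the nuclear and long noncoding RNAs 9 of 20 had a peak (random mean 0.236, 0 of 10000 as high). They included TUG1 at 15.3, FTX at 8.97 over 48 peaks and NEAT1 at 8.72 over 15. MALAT1 was at 2.16, where the control level inferred from fold and p was 20. The random mean is low because few lncRNA genes (0.497%) had a peak, with summits in protein-coding spans not counted for them. The median best fold of this list was 5.07, against 5.76 for random genes with a peak (9249 of 10000 as high). Of the replication-dependent histones 11 of 17 had a peak (random mean 0.343, 0 of 10000 as high), including H4C3 at 31.5, H1-3 at 22.03, H1-4 at 20.4 and H4C8 at 16.2. Histone genes are a multigene family, so their values are uncertain. Of the small structured RNAs 5 of 17 had a peak (random mean 0.682, 0 of 10000 as high), namely RNU5A-1 at 11.1, SCARNA2 at 7.17, RMRP at 6.27, RN7SK at 5.34 and RPPH1 at 5.07. Several of these also belong to multicopy families and are uncertain for the same reason. In none of the 11 lists above the random lists did the median best fold lie in the upper 2.5% of random lists, a comparison that says little for the small structured RNAs, where 73.3% of the random genes were members of the list.

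The remaining groups were not above the random lists. None of the 57 listed ribosomal protein genes had a peak, although 1807 of 10000 random lists also had none. Of 20 housekeeping and abundant mRNAs YWHAZ (7.46) and PKM (4.30) had a peak (random mean 0.972), and of 12 immediate early genes KLF6 (10.1) did. The 22 lung epithelium markers, the 18 blood and immune markers and the 15 neuron, muscle and liver markers had none, as did 808, 1768 and 664 of 10000 random lists. Of the 477 zinc finger genes whose symbol is ZNF and a number alone, 88 had a peak (random mean 78.0, 1032 of 10000 as high), led by ZNF460 (20.7), ZNF121 (15.7) and ZNF217 (14.9). Peaks require an expressed RNA, and expression was not measured in this list, so these counts combine expression with enrichment.

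**Figure D2:**
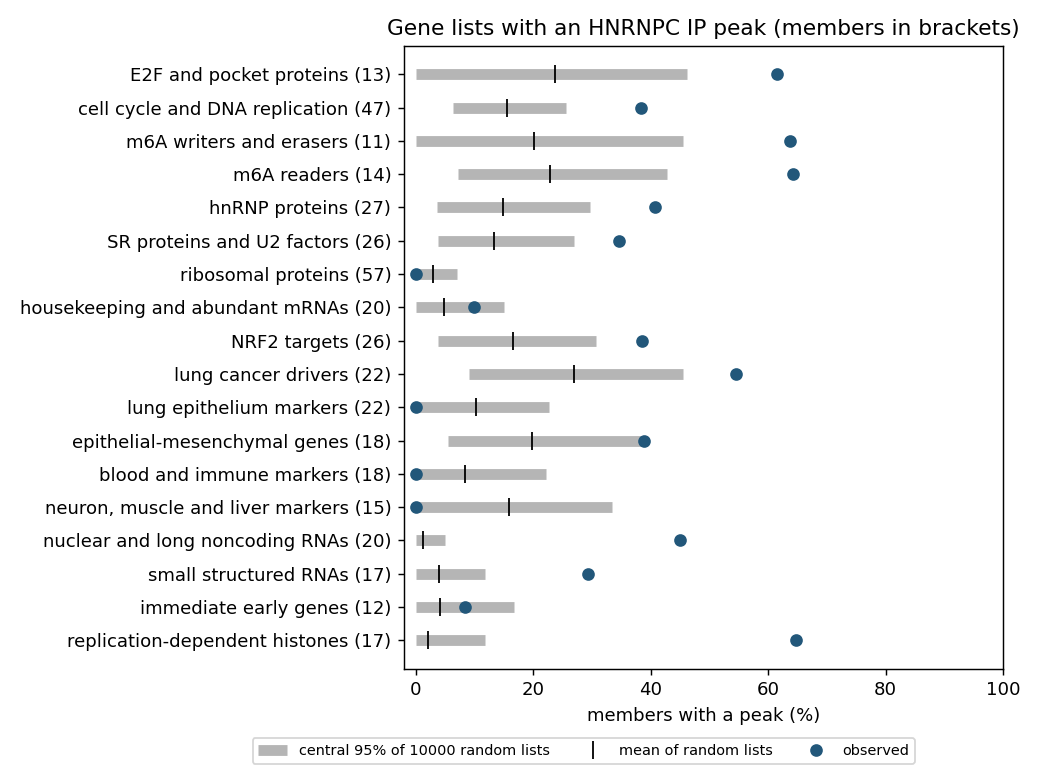
Share of each gene list's members with a peak (blue points, x axis in percent; number of members in brackets) beside the mean (black ticks) and the central 95% (grey bars) of 10000 random lists matched on biotype and gene span. Of the 18 lists drawn, the 11 above the random lists include the histones (64.7%) and the E2F and pocket proteins (61.5%); the zinc finger family is not drawn.

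Peaks were found more often in genes of longer span. The share of protein-coding genes with a peak was 1.497% (95% exact interval 1.01 to 2.13%) in the shortest of 10 span classes and 38.6% (36.4 to 40.7%) in the ninth class, of median span 109.9 kb. It was 32.3% in the longest class. Peaks per Mb of span rose from 9.26 in the third class to 31.3 in the seventh, and were 8.68 in the longest.

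**Figure D3:**
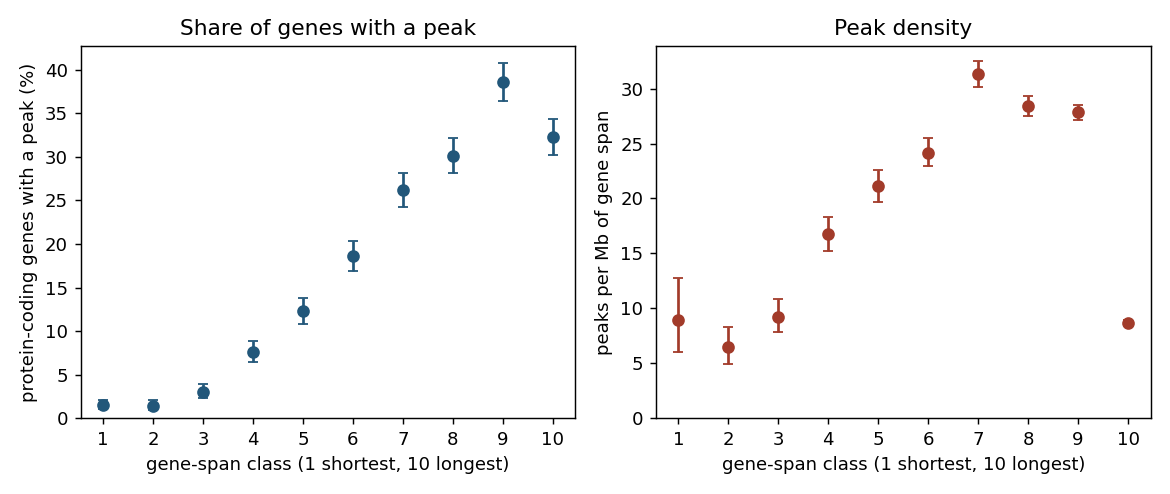
Share of protein-coding genes with a peak (left, percent) and peaks per Mb of gene span (right) in 10 classes of gene span from shortest to longest; bars are 95% exact binomial (left) and Poisson (right) intervals, which cover counting error only. The share was highest in the ninth class (38.6%) and the density in the seventh (31.3 per Mb).

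Summits lay near the ends of genes more often than random positions within 2 and 5 kb, in each of 3 classes of peak width. In protein-coding genes of 20 kb or longer, 184 of 462 peaks of 1000 bp or more (39.8%, 95% exact interval 35.3 to 44.5%) had their summit within 5 kb of an end of the span, against a mean of 15.7% and at most 21.2% in 1000 random placements within the same genes. Peaks from 200 bp to under 1000 bp did so in 34.1% of 4322 cases, against a mean of 14.1% and at most 15.8% at random. Within 2 kb the shares were 18.5% for these, against 5.65% at random, 13.0% for the wide peaks, against 6.28%, and 8.68% for peaks under 200 bp, against a mean of 5.10% and at most 5.69%. Peaks under 200 bp lay within 5 kb of an end in 15.01% of 15916 cases, against a mean of 12.8% and at most 13.7% at random, and within 10 kb in 26.1%, against a mean of 25.5% and at most 26.5%. Which end was the 3' end was not resolved here. Random positions took no account of exons, and the input was not analysed in this way. The excess near ends is therefore not shown to be a preference of HNRNPC.

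Peaks were unevenly spread over the chromosomes relative to gene number. Chromosome 15 had 1171 peaks, 1.65 times the number expected from its protein-coding genes, and chromosome 5 had 1585, 1.52 times. Chromosome 19 had 358 peaks, 0.214 times the expected number, and chromosome 22 had 219, 0.421 times. Against summed gene span chromosome 15 remained at 1.53 times and chromosome 5 came to 1.17 times, the ratios of chromosomes 19 and 22 were 0.612 and 0.621, and 4 chromosomes in place of 7 were more than 1.5 times off.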

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

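All tests in this part were chosen after the results were seen. Peaks also lay on contigs that the comparisons above do not use; those with more than 3 peaks are given. Contig GL000195.1 held 20 peaks with a median fold of 5.27, GL000205.2 held 7 with a median of 7.19, and KI270744.1 held 7 with a median of 5.27.

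Histone genes carried peaks in 11 of 17 cases, against a random mean of 0.343. A candidate explanation is unequal recovery of RNAs without a poly(A) tail between IP and control. The small structured RNAs, which also lack a tail, had a peak in 29.4% of cases, more than any random list. Their folds decide nothing, as 73.3% of the random genes they were set beside were members of the same list, and expression was not matched, so this explanation cannot be told apart from others. Reads shared between histone paralogs were not tested, nor was any biological explanation.

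Peaks were commoner in genes of longer span. Chance positions spread evenly over the genome are argued against by a density 61.0 times higher inside than between gene spans. This says nothing on chance positions along transcribed RNA, as peaks require an expressed RNA. A mere gain in positions is argued against for span classes 4 to 9, whose density was 3.25 times that of classes 1 to 3 pooled. For the longest class the density was 1.04 times, so a gain in positions over the shortest classes is not argued against there. Such a gain does not account for the fall from class 9 to class 10. Density there fell from 27.9 to 8.68 per Mb and the share of genes with a peak from 38.6% to 32.3%. Thin control coverage stays open. With only peaks at an inferred control level of 1 or more, the share of genes with a peak in classes 4 to 10 was 10.4 times that in classes 1 to 3. This decides nothing, because a level of 1 is a single control read and the share also grows with the number of positions. Per Mb of span, such peaks numbered 4.83 in class 3, 11.8 in class 7 and 1.99 in class 10. Expression by span class stays open, and no biological explanation was tested.

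None of the 57 listed ribosomal protein genes had a peak. Short gene spans stay possible but were not put to a test that could fail. Random lists of the same span classes had a mean of 1.66 members with a peak, and 1807 of 10000 had none either. No count could therefore have fallen below them, and expression was not matched. A high control level at abundant mRNAs stays open as well. With the most IP reads inferred at any summit, 93, the fold at a control level of 10 could reach at most 4.62, below the list's median of 5.76. Peaks were still called at such levels. At an inferred control level of 10 or more there were 91, with a median fold of 2.49 and a lowest of 1.97, and MALAT1 had 2.16 at a level of 20. The control level at genes without a peak is unknown, so this explanation cannot be told apart from short spans. Reads lost to ribosomal pseudogenes were not tested, and no biological explanation was tested.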

How the results depend on the processing

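The rule that at least as much of a peak lies inside the gene span as outside it, the alternatives to the number of genes with a peak, shared peaks for E2F2 and HNRNPC, summed gene span for chromosomes and other distances to span ends were chosen after seeing the data. Peak number ranged from 18827 (q of 0.001 or less) to 23148 (all contigs), the share of summits inside genes from 98.6% to 98.7%, and protein-coding genes with a peak from 3130 to 3685. The number of lists above random lists was 11 or 12: under q of 0.001 or less and with unmatched lists the epithelial-mesenchymal genes were added, and no list lost its call. Wide peaks lay near an end 2.53 times as often as at random within 5 kb, 2.07 times within 2 kb and 2.03 times within 10 kb. HNRNPC kept 12 to 18 peaks. In 3 cases a value moved. E2F2 had 6 peaks in place of 10 with q of 0.001 or less, as weaker peaks were removed. The share of peaks outside genes above the list's median was 40.8% by fold and 30.6% by −log10 q, and 4 chromosomes in place of 7 were over 1.5 times off when expected from summed gene span; the cause was not tested. Settings that need exons, strand or sequence were not run. With 1 library and unknown depth, the absence of a peak does not show the absence of binding. No paired analysis was possible because each group has 1 library and no result comes from a test between groups.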

Other observations

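All tests in this part were chosen after the results were seen. Among 98 families of protein-coding symbols sharing a letter prefix, each with 20 or more genes, the ZBTB genes, transcription factors with zinc fingers, had a peak in 19 of 42 cases (random mean 7.09, 0 of 10000 random lists as high). The USP genes, ubiquitin-specific proteases, had one in 27 of 77 (random mean 14.97, 8 of 10000 as high), and the NUP genes, nucleoporins, in 13 of 23 (random mean 6.36, 27 of 10000 as high). None of 392 olfactory receptor genes with the prefix OR had one (random mean 14.7). Of the COL genes 3 of 44 did (random mean 13.0, 2 of 10000 as low), and of the IL genes 3 of 85 (random mean 13.4, 1 of 10000 as low). With 98 families screened, some would stand apart by chance, and expression was not matched.

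Of the peaks whose summit lay outside all gene spans, the strongest, on chromosome 5 at 65925769 to 65926836, had a fold of 18.4. Its summit lay 0.491 kb before the start of the ERBIN span, which the peak overlapped. The next, on chromosome 17 at 62065475 to 62065943, had a fold of 13.5, overlapped no gene span and had its summit 0.482 kb beyond MED13. Both of the next had a fold of 11.6: one on chromosome 20 at 4823398 to 4823638 overlapped RASSF2, and one on chromosome 21 at 6722107 to 6722754 overlapped no gene span and lay 51.95 kb and 88.2 kb from the nearest genes. One on chromosome 5, 107671178 to 107672236, with a fold of 10.9, overlapped none and had its summit 0.935 kb beyond EFNA5.

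Fold and p took few distinct values. A hypothesis is that both come from whole IP reads at the summit, scaled to a smaller control library and set against a Poisson background. At a scale of 0.5355, the best of 9001 tried, 100% of all peaks gave a whole IP read number within 0.001. A single solution was found for 99.7% of all peaks. The scales were compared only on peaks with the 300 most frequent pairs of fold and p. On these, the median over scales that were not simple multiples was 0.843% and the highest was 52.4%. On 2491 simulated peaks, with the true scale supplied, 99.4% had a single solution, and of these 100% returned the true number. The search for the scale was therefore not simulated. Simulated control levels were a background value or small whole numbers, so other fractional levels and high levels were not covered. Under this hypothesis the IP library was 1.87 times the size of the control, the median summit held 15 IP reads and the fullest 93, just under 94, or 2 times the inferred read extension of 47 bp, and 69.4% of 23048 peaks had an inferred control level under 1, meaning no control read over the summit. For E2F2 the strongest peak would rest on 30 IP reads at a control level of 1, and 4 of its 10 peaks on no control read; for HNRNPC 17 of 18 would. That the control was the input library is not stated in the sources used here. The folds of such peaks may therefore follow IP coverage more than enrichment over the control.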
